A study of Folsomia candida with 16 samples.

How the data were processed

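The series holds 16 dual-colour arrays of an Agilent design for Folsomia candida. Per the labels, age-synchronized animals, 23 days old and about 30 per jar, were exposed for 2 days at 20 °C and 75% humidity to soil at 50% of its water holding capacity, and total RNA was extracted from all animals of a jar. The amount of soil is 30 g in the protocol and 25 g in the design text, and 4 biological replicates are stated. Cy3- or Cy5-labelled cRNA was made from 500 ng of total RNA. The LUFA2.2 channel carries the word spiked in the sample labels. It was treated as clean LUFA2.2, as the design text has it. The treated channel of the field soils also carries that word where it is labelled with Cy5, but not where it is labelled with Cy3. Both were taken as the same field soil, and a difference between these labels could not be told from dye orientation. Arrays are numbered here by their order within a treatment, since the labels give no replicate numbers, and the labels do not say which LUFA2.2 extracts, if any, were used on several arrays.

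The deposited array files give, per the file headers, the mean intensity of each spot and the median intensity of its local background in both dyes, as raw scanner brightness, besides processed signals that the software had background-subtracted, spatially detrended and dye-normalized with a lowess curve. Per the file headers, the deposited log10 ratio is that of the processed Cy5 signal over the processed Cy3 signal, after this dye normalization by the software; quality marks come with each spot. The authors' processing notes name Agilent Feature Extraction 9.5.1.1 and limma, while the file header names version 9.1.3.1. The deposited series matrix holds log2 ratios that the authors normalized; per array they correlated with the ratios computed here at 0.975 to 0.996 with slopes of 1.06 to 1.17. The header counts 10806 features, of which 10262 spots (5131 probes in duplicate) were analysed and 544 were not among the spots used. Probe names came from the annotation in the files (database match with an e-value of at most 0.01, median 3e-20); 2330 probes had a match and 1026 an informative name. The probe identifiers matched 0 entries of the reference gene table.

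The main test used limma 3.58.1 in R 4.3.3 with the package data.table (version 1.17.8). Mean intensities were background-corrected with normexp and an offset of 50, normalized by loess within each array, given weight 0 where the software marked the spot as non-uniform or as an outlier, and averaged over duplicate spots. Between 1 and 21 spots per array were marked. Ratios were turned to treated over LUFA2.2 and fitted in a single model of all 16 arrays with 4 treatment coefficients and a dye term common to all arrays, which left 11 residual degrees of freedom. P-values are those of limma's moderated test, two-sided, adjusted by Benjamini-Hochberg over 5131 probes within each comparison, with a threshold of 0.05. The same fit gave the 6 contrasts between treatments. A ratio against a channel not above background on any array is given as a bound, from the means of each channel after loess and Aquantile against the higher of the probe's own signal and the lowest signal well above background per array, and no ratio is given where neither channel is or where the bound is under 1. Duplicate spots correlated at 0.672 to 0.985 per array, and arrays of a treatment correlated with a median of 0.291 for Marchienne, 0.162 for Stolberg, 0.26 for Noyelle and 0.775 for cadmium. Of 120 array pairs, 0 were identical. The arrays lie on 8 slides with 2 arrays each and were scanned on 5 days; each slide and each scan day holds a single treatment.

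Genes were named by a rule fixed, with the tests, the gene lists and the other settings to try, before the data were examined. It took the 10 highest and the 10 lowest log2 ratios per treatment among probes past the threshold, with the same sign on all 4 arrays, above background in a channel on all 4 arrays and with an informative name. It also took up to 4 members of each list that passed, the metallothionein, heat shock 70 and vitellogenin probes, and the 3 highest and 3 lowest probes of each contrast. The 28 gene lists were made of keywords for the names, at 1 probe per cluster (the brightest; 19 clusters have 2 probes, of which 7 had both called for cadmium and 1 of these with opposite signs). Lists of at least 3 members were tested with limma's camera and a preset correlation of 0.01, adjusted within a treatment. Of the 3 lists that passed, 0 did so with an estimated correlation. With fry, which tests whether a list's genes move on balance in a single direction and does not compare them with other genes, 19 lists passed.

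The alternatives were a normexp offset of 16, no background subtraction, the software's processed signals without loess, median centring in place of loess, Aquantile scaling between arrays, leaving out dim probes, no weights for marked spots, no dye term, a dye term per slide, the slide as a random block (consensus correlation 0.116), array weights, the series matrix values, a fit of the compared arrays alone, an absolute log2 ratio of at least 1, and leaving out each array. A dye term per slide could be fitted for Stolberg, cadmium and their difference, since the slides of Marchienne and Noyelle hold a single dye orientation. The procedure was tested on simulated data with 200 changed probes: 44.8% of those with a true log2 change of 0.5, 94% of those with 1 and 98.5% of those with 2 were called, the estimates were drawn toward 0 (medians 0.28, 0.61 and 1.03), 6.51% of 169 calls were false, and 0 probes were called in an unchanged treatment.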

Results

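Transcript levels were measured in whole animals of the springtail Folsomia candida, a small soil arthropod, on 16 dual-colour Agilent arrays. Each array compared RNA of animals kept for 2 days in a treatment soil with RNA of animals kept in clean LUFA2.2, a standard reference soil. The treatments were the field soils Marchienne, Stolberg and Noyelle and a soil with added cadmium, with 4 arrays each, 2 in either dye orientation. The study's design text counts 2 polluted field soils and 1 clean field soil, but the labels do not say which is which, so the soils are given here by name alone; the cadmium dose is not stated. Values are log2 ratios of treated over LUFA2.2 animals for 5131 probes of 5112 transcript clusters, given with the standard error (SE) of the fit and n = 4 arrays per treatment unless stated. Gene names are those of the best database match in the array annotation, often a protein of a distant organism, and 2801 probes had no match. No genome position could be given. The median spot intensity per array was 90 to 173 in Cy3 and 87.2 to 380 in Cy5, and 43.1% to 77.6% of probes lay well above background in the treated channel against 55.5% to 71.2% in the LUFA2.2 channel. The number of arrays limits the precision, with a median SE of 0.0825 per treatment.

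The comparison of cadmium with LUFA2.2 shows which transcripts differed after exposure to soil with the added metal. The 2 highest ratios among the named genes were those of an isopenicillin N synthetase and an alpha-aminoadipyl-cysteinyl-valine synthetase probe, enzymes of beta-lactam antibiotic synthesis. Isopenicillin N synthetase, which forms the penicillin ring system, was 63.2-fold higher at probe Fcc00057C1 (log2 5.98 ± 0.635, limma adjusted p = 6.47e-06, higher on 4 of 4 arrays) and 14.3-fold higher at Fcc01821C1 (log2 3.84 ± 0.324). Alpha-aminoadipyl-cysteinyl-valine synthetase, which makes the peptide that isopenicillin N synthetase closes, was 40.7-fold higher at Fcc00170C3 (log2 5.35 ± 0.333, limma adjusted p = 7.52e-08), with a LUFA2.2 signal well above background on 2 of 4 arrays. A further enzyme of this kind, cephalosporin hydroxylase CmcI, was lower (Fcc00074C1Rev, log2 -1.95 ± 0.25, limma adjusted p = 3.13e-05). In the field soils, probe Fcc00057C1 had ratios of -0.63 for Marchienne, -1.04 for Stolberg and -0.27 for Noyelle, none past the threshold.

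Other named genes that rose in cadmium were a protein with the whey acidic protein core (Fcc01910C1, 18.9-fold), a putative membrane protein (Fcc03091C1Rev, 13.2-fold, log2 3.72 ± 0.338), a fibrinogen C domain protein (Fcc00201C1, 9.3-fold), PAPI I (Fcc01108, 9.22-fold), a glycine receptor subunit (Fcc01574C1, 8.28-fold), gastrodianin (Fcc02343C1, 8.07-fold) and thiopurine methyltransferase (Fcc04215, 7.66-fold). PAPI I varied least between these arrays, with a log2 ratio of 3.08 to 3.37 (limma adjusted p = 1.62e-10). Vitellogenin I, a yolk precursor, was 5.94-fold higher (Fcc05618, log2 2.57 ± 0.14, limma adjusted p = 2.55e-08). Heat shock protein 70, a protein-folding chaperone, was at least 1.49-fold higher at Fcc02719 (log2 0.59 ± 0.0645, limma adjusted p = 7.93e-06), a bound because its LUFA2.2 signal lay above background on 0 of 4 arrays. The call ended under median centring in place of loess and without weights for marked spots. The other heat shock 70 probe, Fcc02026, was not well above background in either channel on any cadmium array, so no ratio is given. No probe was named metallothionein.

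Genes that fell in cadmium included enzymes that break down polysaccharides. A putative xylanase was 13.2-fold lower (Fcc04469, log2 -3.73 ± 0.448, limma adjusted p = 1.81e-05) and an endochitinase, which cleaves chitin, 5.64-fold lower (Fcc02522, log2 -2.50 ± 0.442, limma adjusted p = 0.000427). Alpha-tectorin had a log2 ratio of -1.42 (Fcc05235, treated signal well above background on 2 of 4 arrays), ankyrin -1.41 (Fcc01237C1), a poly (3-hydroxybutyrate) depolymerase -1.34 (Fcc00717, treated signal well above background on 1 of 4 arrays), a methyltransferase -1.33 (Fcc01512C1) and cathepsin O, a cysteine peptidase, -1.23 ± 0.0887 (Fcc03906, limma adjusted p = 2.13e-07). Cuticle protein 2, of the exoskeleton, had -1.35 (Fcc04335C1), a call that ended under median centring. Lectin 2a also had -1.35 (Fcc00508C1, limma adjusted p = 0.0379), a call that ended without Cadmium 1, 2 or 4. Another probe named lectin 2a pointed the other way without passing (Fcc02832C1, 0.25 ± 0.173, limma adjusted p = 0.275).

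In all, 2364 of 5131 probes (46.1%) passed for cadmium, 1234 higher and 1130 lower, and 450 of them changed at least 2-fold, 314 higher and 136 lower. Of the probes called, 1289 had no database match. Under median centring 1182 probes passed, 589 higher and 593 lower. With processed signals 2052 passed, 880 higher and 1172 lower, so the balance of directions turned.

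**Figure D1:**
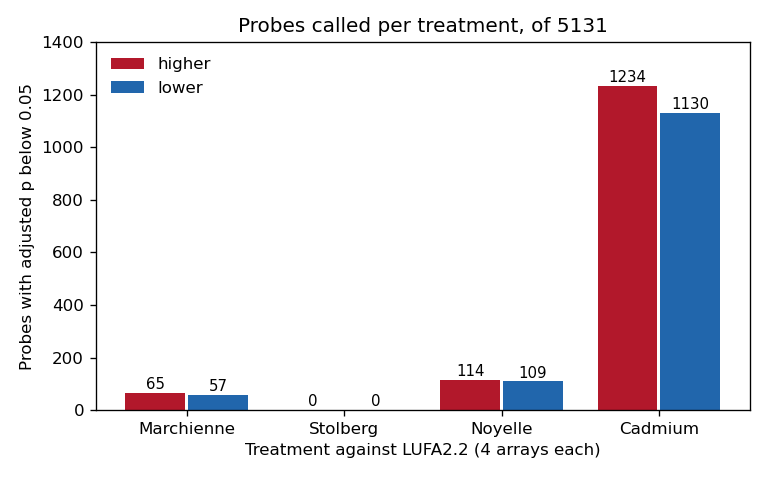
Number of probes with a limma adjusted p below 0.05 (vertical axis) in each treatment against LUFA2.2 (horizontal axis, 4 arrays each), of 5131 probes. Red bars count probes higher and blue bars probes lower in the treated animals: 1234 and 1130 for cadmium, 114 and 109 for Noyelle, 65 and 57 for Marchienne and 0 for Stolberg.

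Among the gene lists fixed in advance, antibiotic biosynthesis was higher in cadmium, with 7 of 10 members higher and 0 lower (median log2 0.20, mean 1.64, camera adjusted p = 0.0194). With an estimated correlation its adjusted p was 0.674, and with the software's processed signals 0.117. The list's keywords leave out cephalosporin hydroxylase CmcI, which was called lower, and 3 of its members were well above background in neither channel, 1 of them called. Of its members that rose, a beta-lactamase, at least 1.1-fold higher (Fcc01834, limma adjusted p = 0.0155), belongs to a class of enzymes that degrade these antibiotics, and another synthetase probe was at least 1.37-fold higher (Fcc00590C1, limma adjusted p = 0.000766), a call that ended with processed signals, under median centring and with the cadmium arrays fitted alone. No other list passed for cadmium, with camera adjusted p from 0.241 to 0.982, so the following are counts of single genes; under median centring ribosomal proteins, the respiratory chain and muscle and cytoskeleton passed as well, all higher. Muscle and cytoskeleton had 6 of 12 members higher and 0 lower, among them muscle-type acylphosphatase (Fcc01488C1, log2 2.04 ± 0.268), myosin 2 light chain (Fcc01638, 1.50 ± 0.107) and troponin C 2 (Fcc04074, 1.46 ± 0.157). ABC transporters, which export compounds from cells, had 5 of 8 higher and 1 lower, among them 1 at least 2.24-fold higher (Fcc00181C1, limma adjusted p = 1.03e-05) and 1 at least 2.13-fold higher (Fcc05819, limma adjusted p = 7.38e-07), whose LUFA2.2 signals were above background on 0 of 4 arrays. Neuronal genes had 5 of 9 higher and 2 lower, with a nicotinic acetylcholine receptor subunit at 1.22 ± 0.0928 (Fcc00279C1). Peptidase inhibitors had 5 of 8 higher and 1 lower, and 2 probes named cystatin A2 moved apart (Fcc02429C1 at 0.98, Fcc01415 at -1.08).

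Of the detoxification and stress lists in cadmium, glutathione S-transferases had 6 of 18 members higher and 0 lower, and cytochrome P450 had 5 of 15 higher and 1 lower, with CYP15A1 at 1.39 ± 0.167 (Fcc02595). The medians of these lists, 0.03 and 0.02, turned to -0.03 and -0.04 under median centring. That setting also moved the median of all probes in cadmium from 0.00206 to -0.0594. The turn of sign therefore shows no change of direction relative to the other probes. Of their members, 6 of 18 and 6 of 15 were well above background in neither channel. With the main scaling, the other members had medians of 0.249 and 0.221. Heat shock and chaperones had 4 of 14 higher and 1 lower. Oxidative stress had 4 of 12 higher and 2 lower, with Cu/Zn superoxide dismutase at 0.98 ± 0.221 (Fcc01344) and Mn superoxide dismutase at -0.29 ± 0.043 (Fcc03714). UGT and sulfotransferase had 0 of 3 called, and metal binding, with ferritin alone, 0 of 1. All members of both lists were well above background in neither channel, so these counts do not show an unchanged level. Ion and metal transport had 1 of 2 higher, a calcium-transporting ATPase (Fcc06092, 1.32 ± 0.276).

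The remaining counts in cadmium were 15 of 40 members higher and 3 lower for ribosomal proteins, where a ribosomal protein kinase (Fcc04024) is 1 of the lower, 2 of 14 higher and 3 lower for translation factors, 1 of 18 higher and 3 lower for proteasome and ubiquitin, and 3 of 15 higher and 2 lower for the respiratory chain. They were 1 of 10 higher and 1 lower for glycolysis and citrate cycle, 4 of 24 higher and 3 lower for lipid metabolism, 1 of 6 higher and 2 lower for cuticle and chitin, and 0 of 1 for moulting hormone. Well above background in neither channel were 7 of 10 glycolysis and citrate cycle members and the 1 moulting hormone member. Vitellogenin and egg had 1 of 3 higher, peptidases 4 of 17 higher and 3 lower, carbohydrate digestion 1 of 10 higher and 4 lower, lysosome 0 of 7 higher and 1 lower, and innate immunity 1 of 8 higher and 2 lower. Cell cycle and DNA repair had 0 of 4 higher and 2 lower, endosymbiont and bacteria 0 of 14 higher and 1 lower, and apoptosis had no member on the array. Of the endosymbiont and bacteria members, 11 of 14 were well above background in neither channel. Among the peptidases that rose was Trypsin I (Fcc00536C1, log2 2.41 ± 0.2). Adjusted over the list alone, the counts were the same except 4 higher and 0 lower for heat shock, 0 higher and 3 lower for proteasome and ubiquitin, and 4 higher and 1 lower for lipid metabolism.

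In Marchienne soil against LUFA2.2, 3 of 15 members of the list of mitochondrial respiratory chain genes were called lower, 0 higher and 12 not called. NADH dehydrogenase subunit 5 was 1.66-fold lower (Fcc00793, log2 -0.73 ± 0.0931, limma adjusted p = 0.00538, lower on 4 of 4 arrays), NADH dehydrogenase subunit 4 had -0.57 ± 0.134 (Fcc04995) and a cytochrome c oxidase subunit -0.41 ± 0.08 (Fcc04662Rev). Adjusted over the list alone, 5 members were lower. The list passed as lower (median log2 -0.25, mean -0.24, camera adjusted p = 0.000739), but not with an estimated correlation, where the adjusted p was 0.0771. With the preset correlation it also passed as lower under each of 5 other scalings, with a camera adjusted p from 6.71e-07 to 0.00118; under median centring cuticle and chitin passed as well, also lower (0.0299). Cytochrome c oxidase polypeptide IV, next by its p, had -0.37 ± 0.0957 (Fcc01864C1, limma adjusted p = 0.0602), and the list also holds a vacuolar ATP synthase subunit (Fcc03280C1, -0.36), a proton pump part outside the respiratory chain.

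Outside that list, antimicrobial peptide Alo-2 was 3.41-fold lower in Marchienne (Fcc05968, log2 -1.77 ± 0.354, limma adjusted p = 0.0275), and lectin 2a (Fcc02832C1, -0.79), an E-1 enzyme (Fcc05071, -0.31) and Multiprotein bridging factor 1 (Fcc01217C2, -0.30) also fell. Another probe named lectin 2a pointed the other way without passing (Fcc00508C1, 0.93 ± 0.49, limma adjusted p = 0.33). The highest ratios among the named genes called were those of a chaperonin containing TCP (Fcc01180, 0.70 ± 0.157) and the Hsc70/Hsp90-organizing protein (Fcc04047, 0.56 ± 0.128), both protein-folding genes with a limma adjusted p of 0.0432 and both far higher on Marchienne 2 than on the other arrays. A nuclear valosin-containing protein (Fcc04558C1, 0.46 ± 0.0799), ribosomal proteins S18 (Fcc04438, 0.44) and S12 (Fcc02740C1, 0.36), cytochrome P450 CYP6N3v2 (Fcc00058C9Rev, 0.38), exportin 1 (Fcc02319, 0.38), carbonyl reductase (Fcc01407C1, 0.34 ± 0.0537), raptor (Fcc05007, 0.33) and a secretory pathway calcium transporting protein (Fcc02839, 0.25) also rose. By list, 2 of 14 heat shock members, 1 of 15 cytochrome P450 members and 2 of 40 ribosomal proteins were higher, and 2 of 8 innate immunity members lower. The other lists had 0 called. Well above background in neither channel were all members of UGT and sulfotransferase (3), metal binding (1) and moulting hormone (1). The same held for 7 of 10 glycolysis and citrate cycle members and 9 of 14 endosymbiont and bacteria members. Adjusted over the list alone, ribosomal proteins had 4 higher and 1 lower, innate immunity 1 higher and 2 lower, cuticle and chitin 1 lower, and muscle and cytoskeleton and cell cycle 1 higher each, with the other counts unchanged. Heat shock protein 70 (Fcc02719, 0.05 ± 0.0645, well above background on 1 of 4 arrays in either channel) and vitellogenin I (Fcc05618, 0.20 ± 0.14) did not pass.

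Marchienne had 122 probes called, 65 higher and 57 lower, 10 of them lowered at least 2-fold and 0 raised that much. The count was 38 without Marchienne 1, 57 without Marchienne 2, 56 without Marchienne 4, 53 with the slide as a random block and 0 with median centring or with the Marchienne arrays fitted alone. Of the 17 named genes called, 3 kept the call without each Marchienne array in turn (Fcc04558C1, Fcc01407C1 and Fcc00793).

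**Figure D2:**
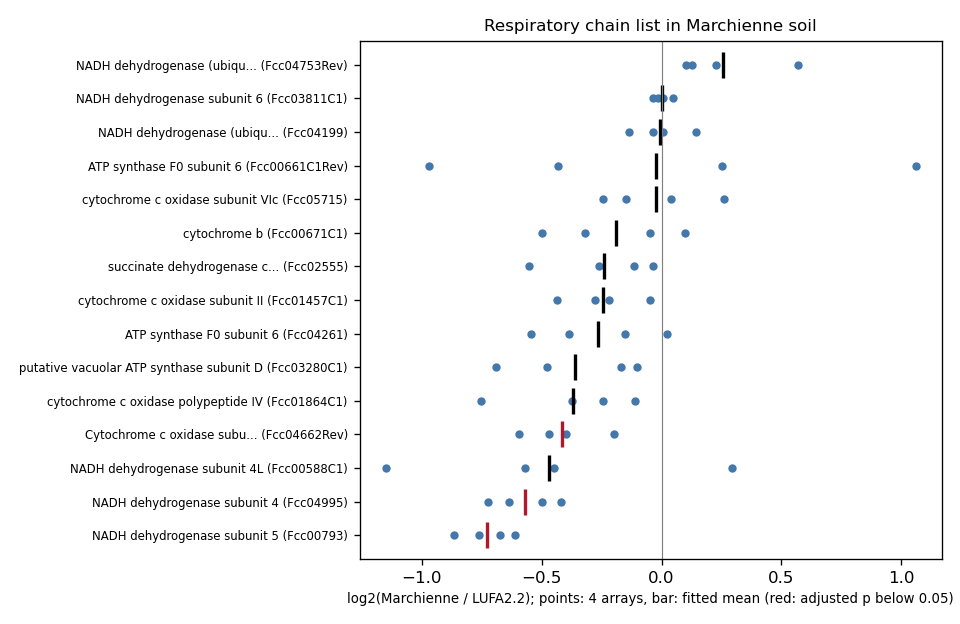
Log2 ratio of Marchienne over LUFA2.2 (horizontal axis) for the 15 members of the respiratory chain list (vertical axis), with a point for each of 4 arrays and a bar for the fitted mean. Red bars mark the 3 members with a limma adjusted p below 0.05, the lowest at -0.73; the list's median was -0.25, and it stayed below 0 under each scaling tried.

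In Stolberg soil against LUFA2.2, no gene passed the test, which does not show that the soil had no effect. The SD of duplicate spots was 0.14 to 0.184 on these arrays, 0.0852 to 0.162 for Marchienne, 0.074 to 0.129 for Noyelle and 0.0888 to 0.162 for cadmium. Antimicrobial peptide Alo-2 had a log2 ratio of -1.93 ± 0.354 (Fcc05968, limma adjusted p = 0.342). In Marchienne its ratio of -1.77, with the same SE, passed, since the adjustment depends on all probes of a comparison. Vitellogenin I had -0.03 ± 0.14 (Fcc05618). No ratio is given for the heat shock 70 probes, as Fcc02026 was well above background in neither channel on any Stolberg array. Fcc02719, well above background on 1 of 4 arrays in the LUFA2.2 channel and 0 in the treated channel, had a bound under 1-fold (0.968). With limma, 0 of 5131 probes were called and 309 had an unadjusted p below 0.05. No gene list passed (smallest camera adjusted p 0.122, peptidase inhibitors), 0 members of any list were called, and adjusted over the list alone 1 member passed in each of moulting hormone (higher), innate immunity (lower) and cell cycle (higher). Well above background in neither channel were all members of UGT and sulfotransferase (3), metal binding (1) and moulting hormone (1). The same held for 7 of 10 glycolysis and citrate cycle members and 13 of 14 endosymbiont and bacteria members. Without Stolberg 4, 3 probes were called, all higher.

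In Noyelle soil against LUFA2.2, the named genes with the lowest ratios were antimicrobial peptide Alo-2 and a hemoglobin. Alo-2 was 5.09-fold lower (Fcc05968, log2 -2.35 ± 0.354, limma adjusted p = 0.0115) and hemoglobin T1 polymer precursor, an oxygen-binding protein, 4.84-fold lower (Fcc04525, log2 -2.28 ± 0.412, limma adjusted p = 0.0171), both on 4 of 4 arrays. A MOCO sulphurase domain protein (Fcc03887C1, -1.06), ADAM metallopeptidase domain 33 (Fcc00971C1, -1.01), a flavin-containing monooxygenase (Fcc04244, -0.99), an inhibitor of growth family member (Fcc04653, -0.87), vitellogenin I (Fcc05618, -0.59 ± 0.14, limma adjusted p = 0.0416), a fatty acid desaturase (Fcc01740, -0.54), myosin 2 light chain (Fcc01638, -0.52) and SEC14-like 2 (Fcc06054, -0.49) also fell. Genes that rose did so by less, led by c12.1 (Fcc01024C1, 0.56 ± 0.0937), translin associated factor X (Fcc00223, 0.39), Der1-like domain family member 1 (Fcc03960C1, 0.36), a predicted flavoprotein (Fcc00543C1, 0.34), Bm44 (Fcc03361, 0.33), an enoyl coenzyme A hydratase (Fcc00729C1, 0.32), an RNA polymerase II subunit homologue (Fcc01537, 0.28), a FIP1L1/PDGFRA fusion protein (Fcc05500, 0.26, LUFA2.2 signal well above background on 2 of 4 arrays) and a charged multivesicular body protein (Fcc06115, 0.23). RFC40, a replication factor subunit, was at least 1.15-fold higher (Fcc01527C1), as its LUFA2.2 signal was above background on 0 of 4 arrays, and its ratio turned to -0.17 under median centring. Heat shock protein 70 did not pass (Fcc02719, -0.05 ± 0.0645), with a treated signal well above background on 3 of 4 arrays and a LUFA2.2 signal on 1.

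Ribosomal proteins were the single list to pass in Noyelle, with 0 of 40 members called, 0 adjusted over the list alone and lower values on balance (median log2 -0.14, mean -0.11, camera adjusted p = 0.0255). With an estimated correlation the camera adjusted p was 0.535, and the fry adjusted p was 0.206. At the preset correlation the camera adjusted p was 0.191 without Noyelle 3 and 0.147 without Noyelle 4. Under median centring the median turned to 0.11, and with processed signals the camera adjusted p was 0.176. Muscle and cytoskeleton passed as lower under both of these scalings (0.0346 and 0.0125), and endosymbiont and bacteria under median centring (0.0118). The members with the smallest p were ribosomal proteins S18 (Fcc04438, -0.33 ± 0.0887, limma adjusted p = 0.051), L24e (Fcc00999, -0.20), P0 (Fcc04202, -0.34) and 15a (Fcc00119, -0.29). In the other lists, members called lower numbered 2 of 12 for oxidative stress, 2 of 24 for lipid metabolism, 2 of 8 for innate immunity, and 1 each of 14 translation factors, 15 respiratory chain members, 3 vitellogenin and egg genes, 8 peptidase inhibitors, 7 lysosome genes and 12 muscle and cytoskeleton genes, and 0 members were called higher. Adjusted over the list alone, muscle and cytoskeleton had 5 lower, respiratory chain 1 higher and 4 lower, peptidase inhibitors 2 lower, neuronal 2 lower, cytochrome P450 1 lower and carbohydrate digestion 1 higher and 1 lower, with the other counts unchanged. Well above background in neither channel were 2 of 3 UGT and sulfotransferase members, 7 of 10 glycolysis and citrate cycle members and 11 of 14 endosymbiont and bacteria members.

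Noyelle had 223 probes called, 114 higher and 109 lower, 15 of them lowered at least 2-fold. The count was 8 without Noyelle 1, 5 without Noyelle 2, 13 without Noyelle 3, 8 with processed signals, 1510 under median centring (243 higher, 1267 lower) and 0 with the Noyelle arrays fitted alone, and of the 20 named genes called, 0 kept the call without each array in turn.

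**Figure D3:**
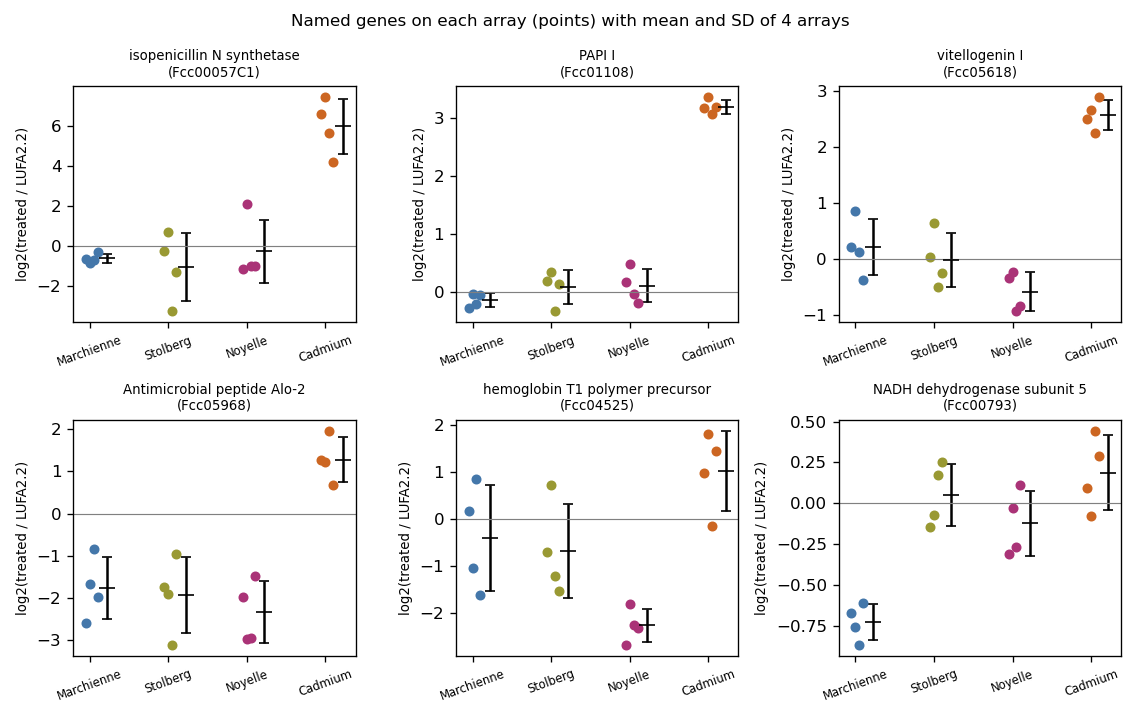
Log2 ratio of treated over LUFA2.2 (vertical axes) on each array for 6 named genes, by treatment (horizontal axes); points are arrays, and the bars beside them give the mean and standard deviation (SD) of 4 arrays. Isopenicillin N synthetase, PAPI I and vitellogenin I were highest in cadmium, with means of 5.98, 3.21 and 2.57; Alo-2 had a mean of -2.35 and hemoglobin T1 one of -2.28 in Noyelle, and NADH dehydrogenase subunit 5 one of -0.73 in Marchienne.

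The treatments were also compared with each other. Isopenicillin N synthetase (Fcc00057C1) was lower than in cadmium by log2 -6.61 in Marchienne, -7.02 in Stolberg and -6.25 in Noyelle (SE 0.898 each, largest limma adjusted p 0.000131), and the putative xylanase (Fcc04469) was higher by 3.62, 3.65 and 4.26 (SE 0.634 each). The synthetase probe Fcc00170C3 differed by -5.47 in Noyelle, where its treated signal was well above background on 1 of 4 arrays. On the Marchienne and Stolberg arrays it was so on 0 of 4. Between the treated channels it was at least 61.3-fold (Marchienne) and 58-fold (Stolberg) lower than in cadmium. The fitted contrasts, relative to LUFA2.2 on the same arrays, were smaller than these, so the bounds hold for the comparison of channels alone. The endochitinase (Fcc02522) was higher than in cadmium by 2.85 in Marchienne and 2.99 in Stolberg, and cephalosporin hydroxylase CmcI (Fcc00074C1Rev) by 2.53 in Marchienne and 2.22 in Noyelle. Lectin 2a (Fcc00508C1) was higher than in cadmium by 2.48 in Stolberg, a call that ended without a dye term, and alpha-tectorin (Fcc05235) by 2.07 in Noyelle. The putative membrane protein (Fcc03091C1Rev) was lower by -4.28 in Marchienne and -4.48 in Stolberg (SE 0.479 each), and the protein with the whey acidic protein core (Fcc01910C1) by -4.94 in Noyelle. With limma, 1958 probes differed between Marchienne and cadmium (940 higher, 1018 lower in Marchienne), 1893 between Stolberg and cadmium (893 and 1000) and 2092 between Noyelle and cadmium (1011 and 1081). Under median centring these counts were 707, 736 and 1322. The share of called probes higher than in cadmium was 48%, 47.2% and 48.3%, and 45%, 46.7% and 52.5% under median centring. With processed signals it was 57.2%, 56.1% and 55.6%, so the balance of directions turned.

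Between the field soils, 200 probes differed between Marchienne and Noyelle, 99 higher and 101 lower in Marchienne. The MOCO sulphurase domain protein (Fcc03887C1, 1.00 ± 0.246), the TCP chaperonin (Fcc01180, 0.88 ± 0.222) and ribosomal protein S18 (Fcc04438, 0.77 ± 0.125, limma adjusted p = 0.0148) were higher in Marchienne, and Snx9l protein (Fcc01283C1, -1.79 ± 0.451), riboflavin kinase (Fcc02840C1, -0.74) and a repressor protein (Fcc03748Rev, -0.72) lower. The count was 97 without Marchienne 1, 59 without Marchienne 3, 13 without Noyelle 1, 5 without Noyelle 2, 79 without Noyelle 3, 93 with the slide as a random block, 3 with processed signals and 0 under median centring. Marchienne and Stolberg differed at 0 probes with limma, with 421 at an unadjusted p below 0.05, and at 1 probe without Marchienne 2. Stolberg and Noyelle differed at 1 probe, Fcc05034C1, named after its values were seen, whose match is an unnamed mosquito protein; it was higher in Stolberg by 1.28 ± 0.165 (limma adjusted p = 0.0185), and the count fell to 0 without Stolberg 1 or 2 or without Noyelle 1, 3 or 4 and was 4 without Stolberg 4. Each slide and scan day held a single treatment, so a treatment could not be told from its scan day in these contrasts. The random slide block allows only for likeness of the arrays within a slide.

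Effects of the treatments were correlated across the 5131 probes, which are not independent replicates; 6 pairs were computed, with a jackknife SE over arrays and no p-value. Pearson's r was 0.516 ± 0.112 for Marchienne and Stolberg (Spearman's rho 0.358) and 0.437 ± 0.219 for Stolberg and Noyelle (rho 0.299). It was 0.0935 ± 0.158 for Marchienne and Noyelle (rho 0.0261), a sign that turned to -0.0143 with processed signals and -0.00725 under median centring. Against cadmium it was -0.113 ± 0.0872 for Marchienne (rho -0.108), -0.168 ± 0.193 for Stolberg (rho -0.222) and -0.253 ± 0.118 for Noyelle (rho -0.228). Simulated treatments without any effect gave an r of -0.0129 with separate LUFA2.2 extracts and 0.51 with fully shared ones, and the labels do not say whether extracts were shared. The simulation gave both channels equal variance, and its covariance with fully shared extracts was 0.0102. The observed covariance was 0.0252 for Marchienne and Stolberg, 0.0217 for Stolberg and Noyelle and 0.0061 for Marchienne and Noyelle. It was below 0 for each field soil with cadmium. Of 147 probes called in both Noyelle and cadmium, 119 had opposite signs, 48 higher and 71 lower in Noyelle, where independent calls would give 25.1 and 26.2. The shared calls fell to 7 without Noyelle 1 (6 opposite), 5 without Noyelle 2 (4), 9 without Noyelle 3 (6), 89 without Cadmium 1 (75), 94 without Cadmium 2 (73), 88 without Cadmium 4 (69), 6 with processed signals (5) and 0 with each treatment's arrays fitted alone. Of 69 probes called in both Marchienne and cadmium, 31 were higher and 20 lower in Marchienne with the opposite sign in cadmium, against 14.3 and 13.7. The shared calls fell to 18 without Marchienne 1, 39 without Marchienne 2, 32 without Marchienne 4, 46 without Cadmium 1, 45 without Cadmium 2 and 0 under median centring. Marchienne and Noyelle shared 8 probes, 3 of them lower in both, 0 higher in both, 3 higher in Marchienne and lower in Noyelle and 2 the reverse. They shared 0 to 15 without each of their arrays in turn (lowest without Noyelle 2, highest without Marchienne 2).

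**Figure D4:**
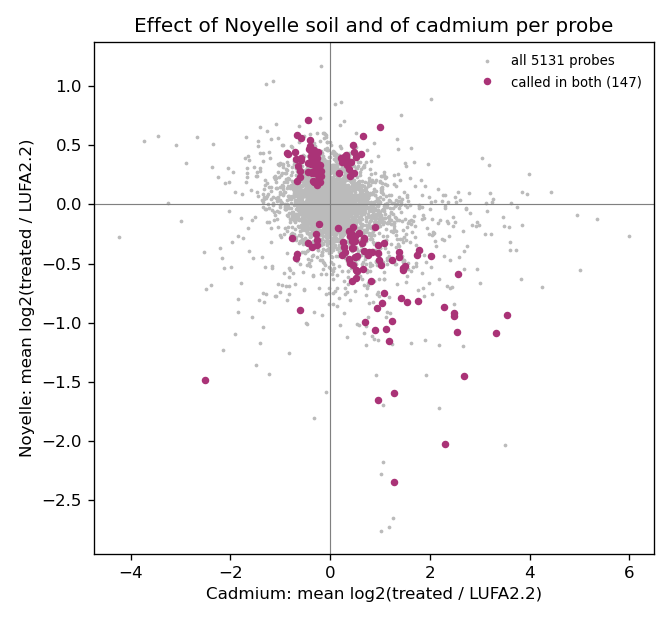
Log2 ratio over LUFA2.2 in Noyelle (vertical axis, mean of 4 arrays) against that in cadmium (horizontal axis, mean of 4 arrays) for 5131 probes (grey), with the 147 probes called in both marked in purple. Of the purple points, 119 lie in the quadrants of opposite sign, 71 of them lower in Noyelle and higher in cadmium.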

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

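The tests of shared LUFA2.2 extracts, within-array loess, dye bias, the mitochondrial genome, the LUFA2.2 channel over all probes called for cadmium, splits by slide and the counts of opposite signs without each array were chosen or sharpened only after the result was seen.

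Noyelle and cadmium effects ran in opposite directions at 119 of 147 probes called in both, counts that fell to 6 of 7 without Noyelle 1, 4 of 5 without Noyelle 2, 6 of 9 without Noyelle 3, 75 of 89 without Cadmium 1, 73 of 94 without Cadmium 2 and 69 of 88 without Cadmium 4. Lower in Noyelle and higher in cadmium were, for example, vitellogenin I (Fcc05618, -0.59 and 2.57) and myosin 2 light chain (Fcc01638, -0.52 and 1.50). The tables argue against shared LUFA2.2 extracts, which can give only a covariance above 0: it was -0.043 ± 0.0234 (jackknife SE), and the correlation of -0.253 ran from -0.318 to -0.184 without each array in turn. They also argue against within-array loess as the whole cause: under median centring the correlation was -0.187 ± 0.102 (-0.26 to -0.119 without each array in turn), although this setting moved the Noyelle count from 223 to 1510. Another state of the LUFA2.2 animals on the Noyelle arrays stays open. Over the 119 probes their LUFA2.2 channel lay 0.124 ± 0.0539 in the cadmium direction, against the Marchienne and Stolberg arrays. But these probes were chosen by their Noyelle ratio, which by itself pushes that channel this way, so the shift decides nothing. Over all 2364 probes called for cadmium, chosen without a Noyelle value, the mean Noyelle effect in the cadmium direction was -0.073. Over these the LUFA2.2 channel shift was -0.0295 ± 0.0225 and the treated channel shift -0.0646 ± 0.0361. Such a state by itself would have put the LUFA2.2 shift above 0. But both channels shifted the same way, and they are compared between slides, so the sign of the LUFA2.2 shift does not decide. For either set of probes, that state and a biological difference between the soils cannot be told apart. Each array has a single LUFA2.2 channel and each slide a single treatment.

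Stolberg effects correlated with those of Marchienne (0.516) and Noyelle (0.437) although 0 probes were called for Stolberg. A dye bias per probe common to the arrays cancels in these effects, as each treatment had 2 arrays in either orientation. With the common dye coefficient regressed out, the correlation was 0.513 ± 0.0942 (jackknife SE) for Marchienne and Stolberg and 0.46 ± 0.193 for Stolberg and Noyelle. This argues against a bias of that pattern that differs only in strength between arrays as the whole cause. A dye bias whose pattern differs between slides could not be tested, since the slides of Marchienne and Noyelle hold a single dye orientation. Array pairs of opposite dye orientation correlated at a median of 0.219 ± 0.0265 and 0.108 ± 0.0897 and those of the same orientation at 0.267 and 0.251. Fully shared LUFA2.2 extracts carrying all of the residual variance allow a covariance of up to 0.0225. The covariance for Stolberg and Noyelle, 0.0217, lay -0.000794 from it with an SE of 0.0141. That for Marchienne and Stolberg, 0.0252 with an SE of 0.0083, lay above it by less than this SE. With equal variance in both channels the simulated covariance was 0.0102. Extracts fully shared in both pairs would also be shared by Marchienne and Noyelle, whose covariance was 0.0061 with an SE of 0.0117. These SEs are too wide to decide, so shared extracts stay open. Effects that field soils have in common against LUFA2.2 stay open as well.

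Respiratory chain genes were lower in Marchienne as a list with the preset correlation (camera adjusted p = 0.000739) but not with an estimated one (0.0771), and 3 of 15 members were called. Signal level was excluded, as 0.04% of 10000 random lists matched on mean signal had a median as low as -0.246. A single Marchienne array was excluded too, with a highest camera adjusted p of 0.00744 at the preset correlation without each array in turn (lowest 0.000542). Fewer transcripts of the mitochondrial genome may be behind it. Its 8 members had a median of -0.255 and the 6 others one of -0.132, with a bootstrap SE of 0.137. The 8 ran from -0.729 (Fcc00793) to 0.000233 (Fcc03811C1). Among them, Fcc00661C1Rev (-0.0225) and Fcc04261 (-0.265) share the name ATP synthase F0 subunit 6. The 6 include the vacuolar ATP synthase subunit (Fcc03280C1, -0.36), which lies outside the respiratory chain. Without it the middle value of the others was -0.0232 (Fcc05715). They ran from -0.371 (Fcc01864C1) to 0.257 (Fcc04753Rev), too wide to decide.

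A sample far from the others was found in 4 of 77 groups of 4 arrays tested (74 of genes, 3 of lists), where chance gives about 1 in 20. The TCP chaperonin Fcc01180 had 1.55 on Marchienne 2 and 0.346 to 0.503 on the other arrays. The Hsc70/Hsp90-organizing protein Fcc04047 had 1.3 on Marchienne 2 and 0.274 to 0.353 on the others. Translin associated factor X (Fcc00223) had 0.475 on Noyelle 2 and 0.345 to 0.365 on the others. Alpha-tectorin (Fcc05235) had -0.806 on Cadmium 2 and -1.64 to -1.57 on the others.

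A difference between treatments, tested as a contrast, was found at 200 probes for Marchienne and Noyelle, 1958 for Marchienne and cadmium, 1 for Stolberg and Noyelle, 1893 for Stolberg and cadmium and 2092 for Noyelle and cadmium. Splits of the 8 arrays of a pair into groups of 4 number 35 with the real split. They take the arrays as independent. Those that keep the 2 arrays of a slide together number 3, too few for a share under 0.05. Not all of the 35 keep 2 arrays of either dye orientation in each group, as the real split does. Their shares therefore do not exclude chance for any pair. For Marchienne and Noyelle, 1 of 35 splits gave as many (highest other 17). That real count of 200 fell to 93 with the slide as a random block, 97 without Marchienne 1 and 59 without Marchienne 3. It fell to 13 without Noyelle 1, 5 without Noyelle 2 and 79 without Noyelle 3. The share was also 1 of 35 for Marchienne and cadmium (highest other 204), Stolberg and cadmium (highest other 1) and Noyelle and cadmium (highest other 1). For Stolberg and Noyelle, 3 of 35 splits gave as many (real count 1, highest other 1). For Marchienne and Stolberg the splits decide nothing, as a real count of 0 is met by all 35 (highest other 2).

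For each treatment against LUFA2.2, the sign flips of 4 arrays give 8 splits, too few for a share under 0.05. The real counts and the highest others were 2364 and 8 for cadmium, 122 and 12 for Marchienne, 223 and 0 for Noyelle, each with 1 of 8 splits as large, and 0 and 1 for Stolberg, with 8 of 8. For the lists passed, the real count and the highest other were 1 and 3 for cadmium (4 of 8 splits as large), 1 and 1 for Marchienne (3 of 8), 1 and 2 for Noyelle (4 of 8) and 0 and 1 for Stolberg (8 of 8). Every split meets a real count of 0, so the shares for Stolberg decide nothing.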

How the results depend on the processing

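The alternatives below were all planned, apart from the field soil mean, the gene lists under other scalings and the counts of probes called with opposite signs, tests chosen after the data were seen. Of 84 named calls (a probe in a comparison, 61 distinct probes), 84 stayed called under Aquantile and with array weights and 47 with processed signals, and Aquantile leaves log ratios within an array as they are, so it tests nothing here. Counts within 1.5 times the value reported are not listed; over the settings run, named probes kept direction and side of the threshold in 1412 cases, lost the call in 364, gained it in 13 and reversed in 1: RFC40 (Fcc01527C1) in Noyelle, -0.168 under median centring. The cause was not tested for any change below, except that a fold criterion can only remove calls. No paired analysis was possible because the labels give no replicate numbers.

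Under median centring the count was 0 for Marchienne, 1510 for Noyelle, 1182 for cadmium, 0 for Marchienne minus Noyelle, 707 for Marchienne minus cadmium, 0 for Stolberg minus Noyelle, 736 for Stolberg minus cadmium and 1322 for Noyelle minus cadmium; 51 of the named calls held and the Marchienne and Stolberg effects correlated at 0.382. With processed signals it was 59 for Marchienne, 8 for Noyelle, 3 for Marchienne minus Noyelle and 0 for Stolberg minus Noyelle, with 47 named calls. Compared arrays fitted alone gave 0 for Marchienne, 0 for Noyelle, 62 for Marchienne minus Noyelle and 0 for Stolberg minus Noyelle, with 41 named calls. An offset of 16 gave 186 for Marchienne and 95 for Noyelle. Without a dye term it was 76 for Marchienne, 116 for Noyelle and 114 for Marchienne minus Noyelle, and with the slide as a random block 53, 77 and 93. Array weights gave 299 for Marchienne, 1046 for Noyelle, 746 for Marchienne minus Noyelle and 4 for Stolberg minus Noyelle, with weights of 0.231 (Marchienne 2) to 1.9. Series matrix values gave 120 for Noyelle. An absolute log2 ratio of at least 1 gave 10 for Marchienne, 15 for Noyelle, 450 for cadmium, 23 for Marchienne minus Noyelle, 528, 496 and 577 for Marchienne, Stolberg and Noyelle minus cadmium, and 46 named calls. Of the gene lists, 3 passed, 0 with an estimated correlation, 19 with fry, 8 under median centring and 2 with processed signals; the ribosomal list in Noyelle reversed under median centring, with a camera adjusted p of 0.436.

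Leaving out an array gave 38 to 108 probes for Marchienne, 0 to 3 for Stolberg (3 without Stolberg 4), 5 to 238 for Noyelle, 1960 to 2202 for cadmium, 0 to 1 for Marchienne minus Stolberg (1 without Marchienne 2), 5 to 234 for Marchienne minus Noyelle, 1659 to 2052 for Marchienne minus cadmium, 0 to 4 for Stolberg minus Noyelle, 1584 to 1864 for Stolberg minus cadmium and 1750 to 2060 for Noyelle minus cadmium. It left 58 to 84 named calls and 2 to 4 lists. Probes called with opposite signs in Noyelle and cadmium numbered 119, and 56 with an offset of 16, 5 with processed signals, 64 without a dye term, 48 with the slide as a random block, 470 with array weights, 68 with series matrix values, 0 with the compared arrays fitted alone, 6 without Noyelle 1, 4 without Noyelle 2, 6 without Noyelle 3, 75 without Cadmium 1, 73 without Cadmium 2 and 69 without Cadmium 4; for Marchienne and cadmium they numbered 51, and 79, 22, 29, 22, 146, 49 and 0 under the same settings in that order, 0 under median centring, 13 without Marchienne 1, 28 without Marchienne 2, 21 without Marchienne 4 and 31 without Cadmium 1. Some scalings moved the median log2 ratio of all probes by more than 0.1: with processed signals it was 0.102 for Marchienne, -0.103 for Noyelle, 0.19 for Marchienne minus Noyelle, 0.262, 0.108 and -0.115 for Marchienne, Stolberg and Noyelle minus cadmium, and under median centring 0.119 for Marchienne minus Stolberg, 0.165 for Marchienne minus Noyelle, 0.113 for Marchienne minus cadmium and -0.199 for Noyelle minus cadmium. The share of called probes that were higher was 51.1% for Noyelle, 37.5% with processed signals and 16.1% under median centring. Leaving out dim probes kept 3881 probes, and signal over background limits what the others can show.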

Other observations

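All tests in this part were chosen only after the results were seen. The mean of the 3 field soils against LUFA2.2 had 95 probes called, 37 higher and 58 lower. Antimicrobial peptide Alo-2 (Fcc05968) had a mean of -2.02 ± 0.205 (limma adjusted p = 0.00125, lower on 12 of 12 arrays) and 1.29 ± 0.354 in cadmium (limma adjusted p = 0.00913). Myosin 2 light chain (Fcc01638) had -0.37 against 1.50 in cadmium, troponin C 2 (Fcc04074) -0.41 against 1.46, phosphoserine aminotransferase 1, an enzyme of serine synthesis (Fcc05461), -0.34 against 1.75, and cystatin A2 (Fcc02429C1) -0.30 against 0.98. Carbonyl reductase (Fcc01407C1) was higher in the field soil mean (0.17) and in cadmium (0.42). The count was 36 without Marchienne 1, 233 without Marchienne 3, 48 without Stolberg 2, 38 without Stolberg 3, 40 without Noyelle 1, 43 without Noyelle 2, 32 without Noyelle 3, 155 without Noyelle 4 and 14 under median centring.

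A hypothesis was that genes lower in the mean of the field soils may respond in the other direction to cadmium. A lower mean does not require a lower value in each soil: NADH dehydrogenase subunit 5 (Fcc00793) was among them with 0.0524 in Stolberg. Of the 58 probes lower in the field soil mean, 32 (55.2%) were called higher in cadmium and 6 lower, against 24% of all probes called higher. The probes were counted as 5.34 independent ones, for a mean residual correlation of 0.173. With counts rounded to whole probes, the 95% interval ran from 14.7% to 94.7%, so chance sharing of signs was not excluded. All ratios are against LUFA2.2, and a state of the LUFA2.2 animals that differs from all other treatments would move them all the same way. It may lie behind the lower field soil ratios, but not by itself also behind the higher cadmium ratios of these 32 probes. Of the 37 probes higher in the field soil mean, 14 were called lower in cadmium and 7 higher, against 22% of all probes called lower.

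Among 21 named probes called in opposite directions in Noyelle and cadmium, 16 were lower in Noyelle; without Noyelle 1, 2 or 3 no more than 6 probes, named or not, were called so. They included NADPH cytochrome P450 reductase (Fcc05374, -0.40 and 0.83), peroxiredoxin V, an antioxidant enzyme (Fcc02435, -0.37 and 0.44), an amino acid permease (Fcc01530, -0.34 and 0.95), prepro ion transport peptide (Fcc05887, -0.24 and 0.57) and fatty acid synthase (Fcc01066C1, -0.19 and 0.46). The other direction held for a homologue of an RNA polymerase II subunit (Fcc01537, 0.28 and -0.60).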
